A study of Oryza sativa with 52 samples.

How the data were processed

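Anthers of 13 rice (Oryza sativa) lines were profiled with and without cold on Agilent one-colour (Cy3) custom arrays, with 2 arrays for each line and treatment and 52 arrays in all. Per the labels, total RNA was used, plants grew in a greenhouse at 25 °C by day and 19 °C by night, and the cold treatment was 12 °C for 4 days at the early microspore stage. Nothing in the labels says that the 2 replicates of a group came from separate plants or pools, so p-values measure the spread between these arrays, which may be technical.

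Per the file headers, each array was read with Agilent Feature Extraction 11.5.1.1, and the design annotation names the IRGSP5 build. The processed signal is an intensity that, per the file headers, was background subtracted, detrended and floored within the array and not scaled between arrays. The median spot and median background signals are intensity values per the file headers with no normalization. The deposited value table of the series holds log2 values that appear to have been quantile normalized between arrays by the authors. Its column medians lay close together, from 5.46 to 5.56, but were not identical. The submitters' processing notes name limma 3.48.3. The background correction behind the deposited table is not given in the sources used here.

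The scanner files were used for the main values, and the deposited table for an alternative. Of the 60968 probes, 37468 are gene probes. Of these, 35968 name 1 gene identifier, covering 27619 genes, and 1500 name several genes or another gene and were left out of the gene tests. Spots marked as outliers were left out, and spots of the same probe were averaged. A probe was kept when it was well above background on both arrays of at least 1 of the 26 groups, which left 48558 probes of all kinds. A gene with several probes was read from the brightest one, which gave 24009 genes tested. Identifiers and descriptions came from the array annotation. None of the 3704 probes with a RefSeq accession matched the RefSeq gene file (0 matched), so it named no gene. Symbols of list members given by identifier were written beside the identifier from general knowledge when the lists were made. Where the array annotation does not itself name the gene, no file used here pairs the identifier with that symbol, and the gene is given as listed under it.

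Values were log2 of the processed signal minus the 75th percentile of the array. Analysis used R 4.3.3, limma 3.58.1 and data.table (version 1.17.8), with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for reading and plotting. limma fitted 1 mean per group over all 52 arrays, with empirical Bayes moderation and a trend in the prior. The contrasts were the mean cold effect over the 13 lines, the cold effect in each line, the F-test of differences of cold effects between lines, each line's cold effect minus the mean of the other 12, and the same kinds of differences between control groups. Tests were two-sided, each contrast was adjusted over genes by Benjamini-Hochberg, and genes were called at an adjusted p under 0.05. Errors are standard errors (SE) of the fit unless stated otherwise. Where no array of a side was above background, the fold is given as a lower bound against the background level. The bound uses the mean of the brighter side, so it does not cover the spread between its arrays.

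The 26 gene lists covered tapetum and pollen wall, meiosis, cold-responsive transcription factors, cold tolerance loci, the circadian clock, floral organs other than the anther, and protein families taken from descriptions. The pollen maturation list was of the last kind. It held families such as polygalacturonases, pectinesterases, profilins and pollen allergens, and its members were not checked for expression in pollen. All lists were tested with camera at an inter-gene correlation of 0.01 on the 23204 genes complete on all arrays. The mean of each list on each array was fitted with limma over the lists, to compare lines. Members were dropped, from the annotation alone, where it named another gene (TDL1A, ACOS12 and COM1) or another family, such as F-box proteins called cyclin-like or glycolipid transfer proteins. The family exclusions go beyond the rule set beforehand, and an alternative keeps every member as written. Genes of the gibberellin and other families are named by their descriptions.

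The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 12 with the largest average rise and the 12 with the largest average fall among called genes of the same sign in all 13 lines and above background on every array of a treatment; up to 4 called members of each list by size of change; a set of genes named in advance whatever their values; for each line, the called genes that differed most from the other lines under cold; and for each line, the called gene that differed most in controls. Genes with no description beyond an identifier were passed over, up to rank 40. A gene outside these rules is stated as chosen after its values were seen.

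The pipeline was tested on simulated data in 23204 genes, 200 of them changed in all lines and another 200 in Nipponbare alone. Recovery by the average contrast was scored on the first set, and by the other comparisons on the second. The average contrast recovered 64.2% of changes of 1.5-fold, 83.6% of 2-fold and 100% of 4-fold, and 5.68% of its calls were wrong. For a single line these shares were 2.99%, 17.9% and 54.5%, with 8.16% of calls wrong. For a single line against the others they were 0%, 8.96% and 43.9%, and for the F-test between lines 0%, 0% and 7.58%. One fit on the real data had been looked at before these simulations, and counts of called genes were known when the explanations in the closing section were chosen.

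The 75th percentile of the processed signal ran from 148 to 1112 on the arrays outside A58, with 45.4% to 75.1% of probes well above background. On the 4 arrays of A58 it ran from 17.0 to 40.2, with 24.1% to 37.0% of probes above background. No spot was saturated (0 on every array). The number of arrays limits the precision, with 2 per group.

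Alternatives were other background and scaling steps, the deposited table, other probe filters, the mean of a gene's probes, array weights, replicate and slide blocks, leaving out each array or line, a prior without trend, line differences as replicates, each line alone, other set tests and other probes. The array weights were equal for the 2 arrays of each group, so they weighed groups and could not mark down a single array. The normexp step, with an offset of 50, used the median spot signal, because not every file used here holds the mean spot signal. Chosen after seeing the data were a 75th percentile over probes above background on all arrays, leaving out A58, leaving out the 2 arrays with the fewest probes above background outside A58, list members as written, and the lines of each scan day alone. Alternatives of scaling and leave-outs kept the main choice of probe for each gene.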

Results

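Gene expression was measured in anthers of 13 rice lines (Nipponbare, Sasanishiki, Koshihikari, Fukoku, A58, PL9, Lambayeque1, Kasalath, Kirara, R45, R75, R85 and H287), without cold and after 4 days at 12 °C. The treatment fell at the early microspore stage, when the tapetum feeds the young pollen. Each line had 2 control and 2 cold arrays, so that 26 arrays stood on each side. The 4 arrays of A58 were dim, with a 75th percentile of 17.0 to 40.2 intensity units against 148 to 1112 on the others. In 12 lines the control arrays lay in places 1 and 2 of a slide and the cold arrays in places 3 and 4 beside them. Nipponbare was spread over 3 slides, and 4 scan days divide the lines. Koshihikari and Fukoku shared a slide, as did H287 and Kirara, PL9 and Sasanishiki, and Kasalath and Lambayeque1, and can be compared within it. A difference between lines on different slides cannot be told apart from one between slides.

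The first question was what cold did on average over the lines. Cold anthers had more transcript of cold-responsive and AP2/ERF transcription factors and less of histones and photosynthesis genes. These 4 list calls rest on camera at a fixed inter-gene correlation of 0.01, and none held with an estimated correlation (adjusted p = 0.42 for each). Among called genes with 1 sign in all 13 lines and above background on every array of a treatment, the largest rise was that of a transferase family gene (Os02g0483500), by 4.33 ± 0.25 log2 (SE, n = 26 cold and 26 control arrays, adjusted p = 1.7e-14), or 20.1-fold. A myb transcription factor (Os06g0728700) rose by 3.46 ± 0.16 log2 and the NAC factor Os11g0184900, of a plant family with many stress-responsive members, by 3.19 ± 0.16 log2. The largest falls among such genes were those of a glyoxalase domain gene (Os05g0171900), by 2.95 ± 0.25 log2, and of the aldehyde dehydrogenases Os01g0756900 and Os06g0592400, by 2.94 ± 0.24 and 2.92 ± 0.11 log2. In all, 6657 of 24009 genes were higher and 5862 lower in cold, 1379 and 1188 of them by 2-fold or more, while the median change over all genes was 0.03 log2. The 2-fold counts were 472 and 473 with normexp and quantile normalization, and 240 and 127 among genes above background on all 52 arrays.

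Of the called genes, 2841 had the same sign in all 13 lines. The largest rises under the same rule also held a SOUL haem-binding protein (Os01g0850900, 3.21 ± 0.21 log2), a beta-amylase (Os03g0141200, 2.91 ± 0.19), an enzyme of starch breakdown, and WRKY transcription factor 10 (Os05g0537100, 2.72 ± 0.41). GDSL lipase Os01g0214600 rose by 2.71 ± 0.28 log2 and NAM-domain factor Os05g0421600 by 2.63 ± 0.21. A heavy metal transport domain protein (Os04g0667600) rose by 2.60 ± 0.24 log2, and a protein phosphatase 2C (Os09g0325700), from a family with members in abscisic acid signalling, by 2.51 ± 0.15. The EF-hand calcium-binding protein Os06g0683400 and C2-domain protein Os09g0571200 rose by 2.47 ± 0.26 and 2.46 ± 0.18 log2, although in Kirara these changed by only 0.003 and 0.001. The adjusted p-values of these 12 genes ran from 2.1e-16 to 1.8e-06. On the falling side stood histone H4 (Os04g0583600, -2.72 ± 0.30 log2), a thioredoxin peroxidase (Os02g0192700, -2.69 ± 0.13), chlorophyll a-b binding protein 2 (Os01g0600900, -2.57 ± 0.17) and a serine carboxypeptidase (Os04g0396800, -2.57 ± 0.23, but -0.45 with its other probe). A pop3 peptide homologue (Os11g0150400) fell by 2.56 ± 0.27 log2, NifU-domain protein Os09g0481800 by 2.49 ± 0.15, an F-box protein (Os03g0116700) by 2.43 ± 0.16, and HMG-box protein Os02g0258200 by 2.39 ± 0.23. A cytochrome c domain gene (Os02g0814400) fell by 2.41 ± 0.11 log2 and was called in each of the 13 lines. The adjusted p-values of the 12 falling genes ran from 2.7e-18 to 8.3e-09. On the IRGSP5 build, the probe of Os02g0483500 lies on chromosome 2 from 17426350 to 17426409. That of Os06g0728700 lies on chromosome 6 from 31902965 to 31903024, and that of Os11g0184900 on chromosome 11 from 4281836 to 4281895.

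**Figure D1:**
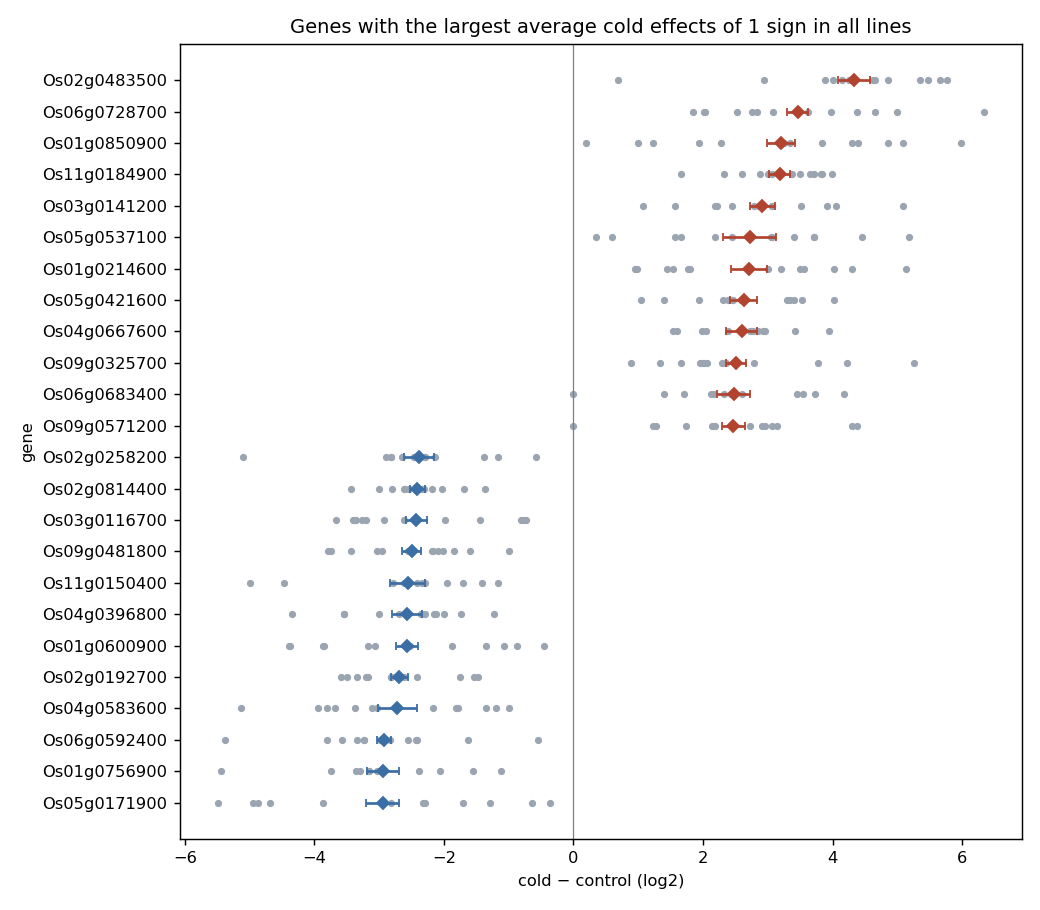
Change in cold (log2, cold minus control) of the 24 genes with the largest average rise or fall among those with 1 sign in all 13 lines and above background on every array of a treatment. Diamonds and bars are the average and its SE, and grey points the 13 lines; Os02g0483500 stands highest at 4.33 and Os05g0171900 lowest at -2.95.

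The average effect was tested with limma over all 52 arrays, and 3986 of the called genes were called in that direction in no single line, where only 2 arrays stand on each side. With the lines of the first scan day alone (R45, R75 and R85), 2407 genes were higher and 2272 lower, and with the 8 lines of the second, 5920 and 5133; the other scan days held 1 line each.

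Regulators of the cold response rose as a group. Of 15 measured cold-responsive transcription factors, 10 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.007, but adjusted p = 0.42 with an estimated correlation). Os01g0884300, a NAM-domain gene listed as NAC6, rose by 2.78 ± 0.22 log2 (adjusted p = 1.2e-11), DREB1C (Os06g0127100) by 2.70 ± 0.45, Os02g0624300, listed as MYB30, by 2.49 ± 0.46 and the CRT/DRE binding factor Os02g0677300, listed as DREB1G, by 2.34 ± 0.40, each higher in 12 of 13 lines. The probes of the last 3 were above background on only 11, 10 and 7 of 26 control arrays, and with normexp the rises of DREB1C and Os02g0677300 were 0.95 and 0.90, and that of Os02g0624300 was also over 1.5 times smaller. The DREB1 proteins bind a dehydration- and cold-responsive promoter element. DREB1B (Os09g0522000) rose by 0.73 ± 0.21 log2 (adjusted p = 0.0043), a call that the mean over its probes did not keep (0.53), while DREB1A (Os09g0522200) stood at -0.71 ± 0.34 (adjusted p = 0.076). The 1 lower member was the ICE1-like gene Os01g0928000, listed as ICE2 (-1.35 ± 0.19 log2), named after its value was seen. In the AP2/ERF family, 35 of 64 members were higher and 1 lower (35 and 1 adjusted over the list alone; adjusted p = 0.0033, and adjusted p = 0.42 with an estimated correlation). Ethylene response factor 3 (Os06g0604000) rose by 1.87 ± 0.19 log2 and the AP2-domain genes Os06g0210300 and Os07g0674800 by 1.94 ± 0.36 and 1.82 ± 0.19.

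Histones and photosynthesis genes fell as groups. None of 36 histone genes was higher (0) and 32 were lower (0 and 32 adjusted over the list alone), with a median of -1.40 log2 (adjusted p = 3.1e-13, and adjusted p = 0.42 with an estimated correlation). Histone H2A genes Os08g0427700, Os03g0279200 and Os01g0502700 fell by 2.82 ± 0.28, 2.67 ± 0.34 and 2.55 ± 0.32 log2. Of 41 photosynthesis genes, 1 was higher and 31 lower (1 and 32 adjusted over the list alone), with a median of -0.74 log2 (adjusted p = 1.3e-12, and adjusted p = 0.42 with an estimated correlation). A type I chlorophyll a/b-binding protein (Os01g0720500) fell by 2.47 ± 0.31 log2, photosystem II protein PsbX (Os03g0343900) by 2.37 ± 0.16 and photosystem I subunit III (Os03g0778100) by 1.65 ± 0.11.

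Markers of anther stage and of other organs were read beside these groups. The photosynthesis list was itself set beforehand as a marker of green tissue that a sample could hold. A different share of such tissue in the samples was not tested apart from a change of expression. Of 12 meiosis genes, 7 were lower and 3 higher (7 and 3 adjusted over the list alone), with a median of -0.94 log2 (-0.50 with normexp). Camera, which compares a list with the other genes, did not call it (adjusted p = 0.38), while limma on the list mean did (-0.46, adjusted p = 0.0057). A DMC1-like gene (Os11g0146800, listed as DMC1B) fell by 1.40 ± 0.27 log2, the pairing gene PAIR3 (Os10g0405500) by 1.39 ± 0.28, the TRIP13-like gene Os04g0479000, listed as CRC1, by 1.18 ± 0.26 and Os03g0800200, listed as MEL1, by 0.97 ± 0.22. The 3 that rose, named after their values were seen, were Os05g0580500, listed as REC8 (0.91 ± 0.08), the DMC1-like gene Os12g0143800, listed as DMC1A (0.64 ± 0.15), and the SPO11-1 homologue Os03g0752200 (0.58 ± 0.11). The DMC1-like genes have 1 probe each, and whether each probe reads its own gene alone was not tested. Of 26 tapetum and pollen wall genes, 3 were higher and 5 lower (3 and 1 adjusted over the list alone; list adjusted p = 0.67). WDA1 (Os10g0471100), needed for anther wax, rose by 0.83 ± 0.10 log2, although another of its probes stood at -0.12, and the receptor kinase MSP1 (Os01g0917500) fell by 0.51 ± 0.09. Not called were an anther-specific protein listed as OsC6 (Os11g0582500, 1.87 ± 0.96, adjusted p = 0.1), a cytochrome P450 listed as CYP703A3 (Os08g0131100, -0.38 ± 0.41, adjusted p = 0.46) and Os03g0168600, listed as CYP704B2 (-0.68 ± 0.31, adjusted p = 0.066). The tapetum regulator TDR (Os02g0120500, -0.05 ± 0.10, adjusted p = 0.73) and a bHLH gene listed as EAT1 (Os04g0599300, -0.47 ± 0.26, adjusted p = 0.13) were not called either. Of 45 genes of the pollen maturation list, which was drawn from family descriptions, 8 were higher and 13 lower (8 and 13 adjusted over the list alone, list adjusted p = 0.49). The polygalacturonases Os05g0279900 and Os01g0636500 rose by 2.66 ± 0.21 and 1.89 ± 0.17 log2. Of 7 genes of other floral organs, 1 was higher and 2 lower (1 and 2 adjusted over the list alone; list adjusted p = 0.98), among them MADS34 (Os03g0753100, -0.39 ± 0.10).

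In carbohydrate metabolism, 10 of 21 starch synthesis genes were lower and 2 higher (10 and 2 adjusted over the list alone; list adjusted p = 0.068). An ADP-glucose pyrophosphorylase subunit (Os01g0633100), which makes the precursor of starch, fell by 1.55 ± 0.30 log2 and starch synthase IIA (Os06g0229800) by 1.41 ± 0.21. Of 51 genes of invertases and sugar transport, 13 were higher and 12 lower (13 and 12 adjusted over the list alone; list adjusted p = 0.75), with a median of 0.04 but a mean of -0.004 log2. Cell wall invertase 2 (Os04g0413500), which splits sucrose outside the cell, fell by 1.94 ± 0.12 log2 and the sugar transporter Os03g0197100 by 1.96 ± 0.14, both in 13 of 13 lines, whereas the invertase Os04g0413200, above background on 6 of 26 control arrays, rose by 1.72 ± 0.24 (0.49 with normexp). Of 8 genes of trehalose metabolism, 3 were higher and 1 lower (3 and 1 adjusted over the list alone; list adjusted p = 0.58), led by trehalose-6-phosphate phosphatase genes Os07g0624600 (1.44 ± 0.14) and Os02g0661100 (1.33 ± 0.26).

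Among hormone genes, 10 of 21 genes of abscisic acid were higher and 4 lower (10 and 4 adjusted over the list alone; list adjusted p = 0.37). An ABA-induced membrane protein (Os05g0381400), above background on 10 of 26 control arrays, rose by 3.75 ± 0.37 log2 (1.68 with normexp), and Anth (Os11g0167800), a pollen-specific desiccation-associated gene, fell by 1.70 ± 0.30. Of 20 gibberellin genes, 7 were higher and 2 lower (7 and 1 adjusted over the list alone; list adjusted p = 0.35), with the gibberellin-regulated family genes Os03g0607200 and Os07g0592000 up by 0.94 ± 0.15 and 0.80 ± 0.13 log2. A gibberellin 20-oxidase 3 homologue (Os07g0169700) rose by 0.51 ± 0.15 log2 (adjusted p = 0.0037), which was not called with the 13 line differences as replicates. The other oxidases of the last steps of gibberellin synthesis named in advance were not called: gibberellin 20-oxidase 1 (Os03g0856700) stood at 0.01 ± 0.25 (adjusted p = 0.98; -0.69 with another probe), and 20-oxidase 2 (Os01g0883800) at -0.23 ± 0.16 (adjusted p = 0.23). The 3beta-hydroxylases Os05g0178100 and Os01g0177400 stood at -0.65 ± 0.30 (adjusted p = 0.07) and -0.27 ± 0.30 (adjusted p = 0.47).

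The circadian clock list had 4 genes higher and 4 lower of 10 (4 and 4 adjusted over the list alone; list adjusted p = 0.58). LHY (Os08g0157600), a myb factor of the morning loop, rose by 2.11 ± 0.14 log2, Os11g0157600, listed as PRR59, by 1.41 ± 0.07, called in each of 13 lines, and the response regulator Os09g0532400, listed as PRR95, by 0.81 ± 0.10, while Os01g0566100, listed as ELF3-2, fell by 0.91 ± 0.10. Of 7 cold tolerance loci, 3 were higher and 1 lower (3 and 1 adjusted over the list alone; list adjusted p = 0.38), among them a Tify-domain gene listed as JAZ9 (Os03g0180800, 0.59 ± 0.08) and a protein kinase listed as CTB4a (Os04g0132500, -0.67 ± 0.17).

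Of the remaining families, 10 of 20 dehydrin and LEA genes were higher and 3 lower (10 and 3 adjusted over the list alone; list adjusted p = 0.17), led by the LEA genes Os01g0314800 (3.31 ± 0.63) and Os01g0705200 (2.39 ± 0.34). Of 52 WRKY factors, 20 were higher and 6 lower (20 and 6 adjusted over the list alone; list adjusted p = 0.068), with WRKY53 (Os05g0343400) up by 3.20 ± 0.34 log2. Of 185 heat shock proteins and chaperones, 60 were higher and 46 lower (62 and 47 adjusted over the list alone; list adjusted p = 0.7). An RbcX chaperonin (Os03g0807900) rose by 3.24 ± 0.30 log2 and a DnaJ protein (Os01g0606900) fell by 2.84 ± 0.14. Of 39 antioxidant enzymes, 17 were lower and 9 higher (17 and 9 adjusted over the list alone; list adjusted p = 0.091), with a nectarin-like superoxide dismutase (Os01g0249200) at -3.46 ± 0.26 and an ascorbate peroxidase (Os07g0694700) at -1.53 ± 0.11. Of 47 glutathione S-transferases, 15 were higher and 7 lower (15 and 7 adjusted over the list alone; list adjusted p = 0.43), with Os01g0353400 and Os01g0369700 up by 2.72 ± 0.25 and 2.61 ± 0.18 log2. Of 29 cyclins and their kinases, 8 were higher and 8 lower (8 and 8 adjusted over the list alone; list adjusted p = 0.69), with a median of 0.07 but a mean of -0.20 log2. The mitotic B-type cyclins Os06g0726800 and Os05g0493500 fell by 2.03 ± 0.23 and 1.74 ± 0.24 log2.

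Of 286 ribosomal protein genes, 56 were higher and 84 lower (55 and 83 adjusted over the list alone; list adjusted p = 0.12), from 1.92 ± 0.17 log2 in Os07g0530400 (0.59 with normexp) to -1.79 ± 0.14 in Os10g0407100. Of 51 lipid transfer proteins, 11 were higher and 17 lower (11 and 17 adjusted over the list alone; list adjusted p = 0.58), with Os05g0550600 at 2.01 ± 0.20 (0.98 with normexp) and Os03g0794000 at -2.23 ± 0.51. Of 59 pathogenesis-related proteins and chitinases, 17 were higher and 9 lower (16 and 9 adjusted over the list alone; list adjusted p = 0.38), with a chitinase (Os01g0860400) at 1.68 ± 0.36 and a thaumatin (Os11g0703100) at 1.57 ± 0.18. Of 53 expansins and xyloglucan enzymes, 16 were higher and 13 lower (16 and 13 adjusted over the list alone; list adjusted p = 0.98), with xyloglucan enzymes Os04g0604300 at 2.58 ± 0.38 and Os09g0395600 at -1.99 ± 0.29. Of 48 proteasome genes, 15 were higher and 10 lower (15 and 10 adjusted over the list alone; list adjusted p = 0.67), with beta subunit 1 (Os08g0529100) at 0.83 ± 0.11 and the activator Os06g0301300 at -0.81 ± 0.06. Sizes depended on the processing: with normexp, 44 of 133 average effects of genes named by the rules were over 1.5 times smaller, as were 17 of 22 differences of a line from the others and 9 of 13 between controls. That alternative changed the background step, the scaling (to quantile) and the spot signal used together. Quantile normalization alone left the average 2-fold counts within 1.5 times of the main ones. The background step, with its offset, and the spot signal were not tested apart from each other. With another probe, 16 of 53 average effects were over 1.5 times smaller or reversed. The list p-values above are from camera unless said otherwise; limma on list means, which asks whether a list moved rather than whether it moved more than other genes, called 17 of the 26, 11 higher and 6 lower. None was called by camera with an estimated correlation (0), and the median of 1 changed sign under another scaling, that of expansins under normexp (-0.01).

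The second question was how the lines differed in their response. Cold changed the most genes in PL9, where 2919 were higher and 2669 lower, and the fewest in R85, with 302 and 226. The other lines had between 753 (Sasanishiki) and 2338 (Kirara) called genes. The shift of all genes was largest in PL9, with a median of 0.12 log2. The spread of the log2 changes, after 1 error pooled over the lines was taken off, was 1.32 in PL9, 1.00 in Koshihikari and 0.40 in A58. With each line's own replicate variance taken off it was 1.23, 0.96 and 0.43. The A58 value, from dim arrays, was 1.17 under quantile normalization and with the deposited values, and 0.63 with normexp. Correlations of the responses across genes, in which genes are not replicates, ran from 0.05 (Nipponbare and Kirara) to 0.61 (Koshihikari and Kasalath), with a median of 0.39 over 78 pairs. PL9 was not first with array weights (4062, against 7200 in Nipponbare and 5703 in Lambayeque1), under quantile normalization (4670, against 4794 in A58), with the deposited values (4607, against 4764 in A58) or with the arrays of a line alone (541, against 7105 in Nipponbare and 3168 in Lambayeque1). Nor was R85 always last: with array weights it had 2524 genes, against 60 in Kirara and 282 in A58, and the arrays of a line alone gave 0 in R85 and 5 other lines. These counts rest on 2 arrays a side: without 1 PL9 array, control 2, the PL9 count was 2693, and each other line has at least 1 array whose removal moved its count by over 1.5 times. The array weights were equal within each group, so the ranks under them show a weighing of groups and not of single arrays.

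**Figure D2:**
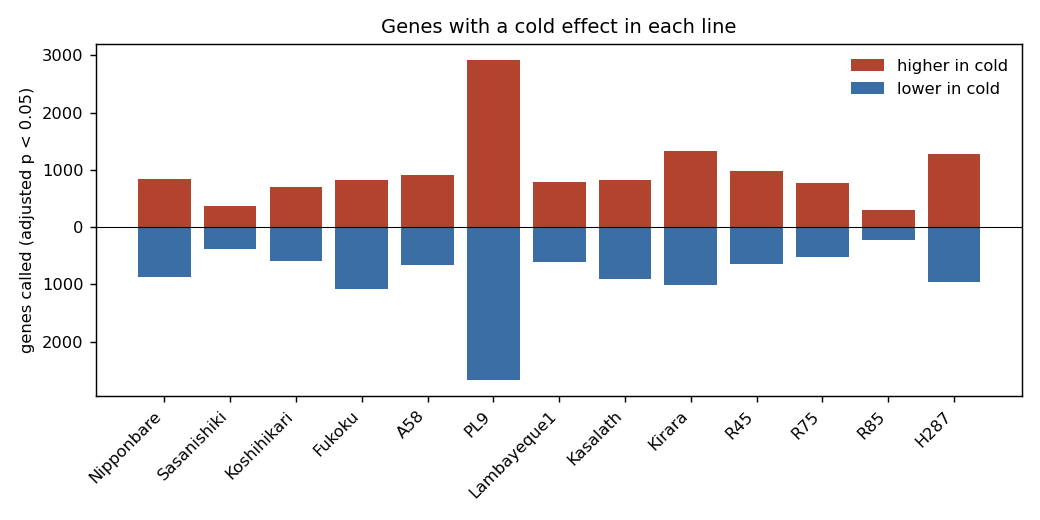
Number of genes called at an adjusted p under 0.05 in each line, with those higher in cold drawn above 0 and those lower in cold drawn below. PL9 stands highest with 2919 genes higher and 2669 lower, and R85 lowest with 302 and 226.

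Of the 4 lists called on average, 1 differed between lines in its cold effect. This was the mean of the photosynthesis list (limma F-test, adjusted p = 0.00017; cold-responsive transcription factors 0.38, AP2/ERF 0.38, histones 0.43), with -2.26 ± 0.30 log2 in PL9, -1.92 ± 0.30 in Fukoku and -1.72 ± 0.30 in H287, against 0.28 ± 0.30 in R75 and -0.01 ± 0.30 in A58 (n = 2 cold and 2 control arrays each). Against the other lines, PL9 lay lower by -1.53 (adjusted p = 0.001) and Fukoku by -1.16 (adjusted p = 0.025), and R75 lay higher by 1.23 (adjusted p = 0.013). The photosynthesis list was also set beforehand as a marker of green tissue, so these differences cannot be told apart from differing amounts of it in the samples. Single lines were also compared with the rest where the F-test made no call. In Kirara the mean of the cold-responsive transcription factors lay below that of the other lines by -1.95 log2 (adjusted p = 0.02), that of dehydrins by -2.16 (adjusted p = 0.02) and that of AP2/ERF factors by -1.01 (adjusted p = 0.041). The clock mean of A58 lay above the others by 0.69 (adjusted p = 0.032). Each of these 7 differences lost its call without some 1 array: without Kirara control 1, which had few probes above background (45.4%), the Kirara differences were -1.67, -1.27 and -0.65. Without Kirara cold 1 or cold 2 the calls were lost with little change in value. PL9 stood at -1.26 without its control 2, Fukoku at -0.67 without its cold 2 (and lost the call without either control), and R75 at 1.00 without its control 2 (and lost it without either cold array). A58 lost its call without any 1 of its arrays, the lowest value being 0.60.

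**Figure D3:**
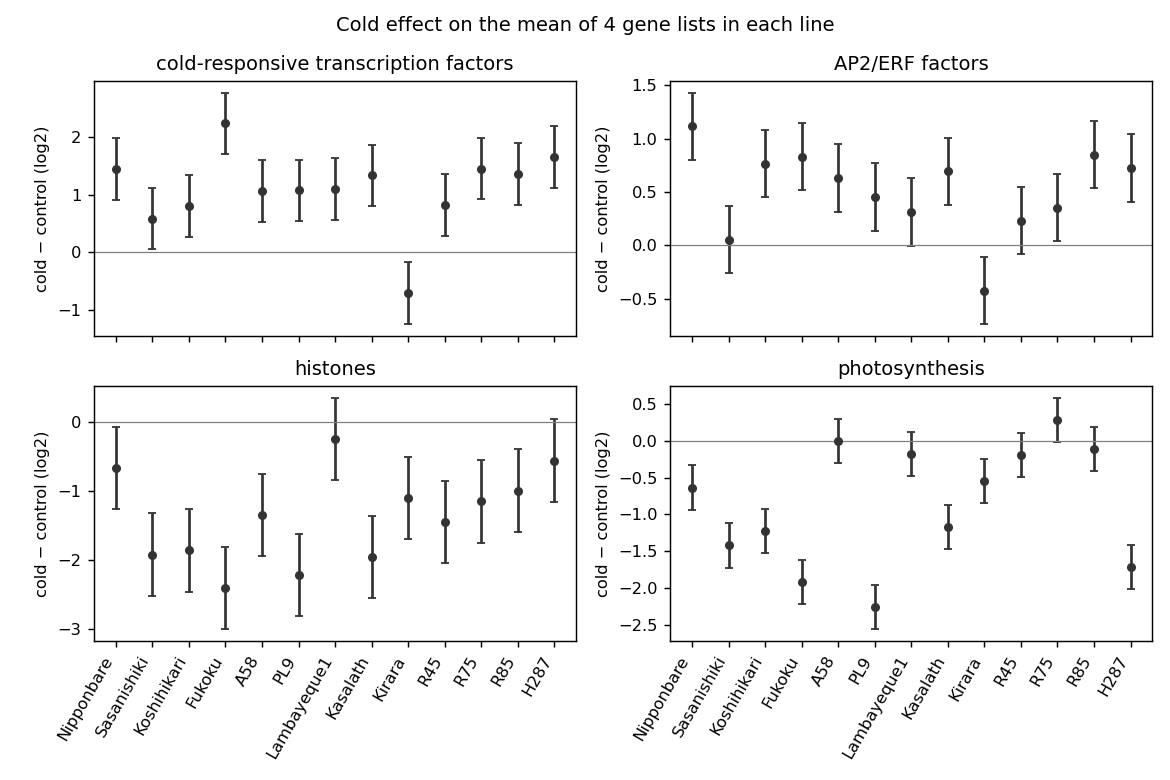
Cold effect on the mean of 4 gene lists in each line (log2, cold minus control), with points for the estimate and bars for its SE from 2 cold and 2 control arrays. Cold-responsive transcription factors lie above 0 except in Kirara (-0.70), and photosynthesis runs from -2.26 in PL9 to 0.28 in R75.

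Single genes also answered unlike the other lines in the size or direction of their change. Folds given for them are cold against control within the line, and log2 differences are against the other lines. In PL9, GDSL lipase Os04g0650200 was at least 760-fold higher in cold (adjusted p = 0.0023 against the other lines), and an eggshell family gene (Os05g0498200) at least 5647-fold lower (adjusted p = 8.7e-06). The bound for Os04g0650200 is from the mean of 2 PL9 cold arrays that lay far apart (SD 3.42 log2). In Fukoku a nitrate transporter (Os03g0103000) was at least 340-fold higher (adjusted p = 0.002), and in Koshihikari a lipid transfer family gene (Os03g0251000) at least 656-fold higher (adjusted p = 0.034), with a xylan endohydrolase (Os05g0319900) lower than in the other lines by -4.46 ± 0.87 log2 (adjusted p = 0.039). In Nipponbare a homologue of the water-stress gene RAB21 (Os11g0454300) exceeded the other lines by 7.75 ± 1.56 log2 (adjusted p = 0.011) and a Rop exchanger (Os01g0675000) fell below by -7.35 ± 0.87 (adjusted p = 2.5e-05). In R75 sedoheptulose-1,7-bisphosphatase (Os04g0234600), an enzyme of the Calvin cycle, was at least 43.2-fold higher (adjusted p = 2.4e-05) and a cytochrome P-450 (Os07g0603700) at least 38.0-fold lower (adjusted p = 0.039). Os04g0234600 also rose in the other lines, by 1.21 log2 on average, and R75 exceeded them by 4.51 ± 0.54. In R45 a scramblase (Os04g0599400) exceeded the others by 4.86 ± 0.66 log2 (adjusted p = 0.00087), and a WRKY factor (Os05g0565900) was at least 11.7-fold lower (adjusted p = 0.037).

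In Lambayeque1 an early light-inducible protein (Os01g0246400) was at least 165-fold higher, and a proline transporter (Os01g0621200) lay below the other lines by -6.15 ± 1.46 log2. The rise of Os01g0246400 was shared: it was called in 8 lines, and the other lines rose by 3.28 log2 on average. Lambayeque1 exceeded them by 4.64 ± 0.89 log2. In Kasalath an AAA ATPase (Os12g0639400) exceeded the others by 6.90 ± 1.53 log2, and a heavy metal transport domain gene (Os10g0532300) was at least 10.6-fold lower. In A58 a class II heat shock protein (Os01g0184100) exceeded the mean of the others by 3.57 ± 0.68 log2, and an aquaporin (Os09g0541000) was at least 22.7-fold lower. The heat shock protein rose slightly more in Nipponbare (2.25 log2) than in A58 (2.19). In Kirara a homologue of the replication factor MCM3 (Os05g0476200) exceeded the others by 3.78 ± 1.03 log2, and GDSL lipase Os06g0725200 was at least 220-fold lower. The Kirara controls behind the bound for Os06g0725200 had an SD of 2.13 log2. The rise of the MCM3 homologue within Kirara was itself not called (1.84 log2, limma adjusted p = 0.26). In H287 the Tify-domain gene Os03g0180800 exceeded the others by 1.61 ± 0.30 log2 and an IN2-2 homologue (Os04g0338000) lay below by -2.08 ± 0.35. In R85 an aspartic proteinase (Os12g0263800) was at least 4.12-fold lower, a difference from the other lines of -1.99 log2 that was -0.03 with normexp and -0.39 over the mean of its probes; Sasanishiki gave no gene that met the rule. The adjusted p-values of the genes of these lines against the others ran from 0.0067 to 0.049. Of the 22 line-specific genes, 17 lost the call without at least 1 array of their line. Os01g0675000, Os05g0498200, Os04g0599400 and Os04g0234600 stayed called without any 1 of them. Os03g0103000 had a value on only 1 Fukoku cold array, so the leave-out that would decide gave no value. Os05g0319900 in Koshihikari controls and Os04g0338000 in H287 cold also had a value on 1 array alone. The MCM3 homologue stood at 0.70 without Kirara control 1.

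The F-test called 1151 genes whose cold effect differed between lines, and 3047 genes differed from the other lines in at least 1 line. PL9 had 1897 of these calls, Kirara 476, A58 325 and Nipponbare 311, and the remaining lines 116 or fewer. The Kirara count was 20 without control 1 and 5115 without control 2, the PL9 count 542 without control 2, and the H287 count, 6 in the fit, was 1017 without its cold 1. The F-test gave 691 genes without control 1 of Nipponbare, 4220 without control 2 of Kirara, 355 with a replicate block and 6943 with array weights.

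The lines also differed before any cold. In R75 controls the tapetum list lay below that of the other controls by -2.72 log2 (adjusted p = 0.0027), and the meiosis list above by 1.66 (adjusted p = 0.0027). A male sterility protein 2 homologue, listed as DPW (Os03g0167600), was not above background in R75 controls, and lay below the others by -10.25 ± 1.95 log2. Its values there exceeded the level used for lower bounds, so this is an estimate and not a bound. The meiosis mean was also higher in Kasalath controls (1.35, adjusted p = 0.013) and lower in Nipponbare (-1.30, adjusted p = 0.01), Kirara (-1.11, adjusted p = 0.021) and A58 (-0.91, adjusted p = 0.037). In Kirara controls the cold-responsive transcription factors lay above the other controls by 1.27 log2 (adjusted p = 0.02), and an alpha-amylase 3D homologue (Os08g0473900), above background on 10 of the 24 other controls, by 8.73 ± 1.49 (adjusted p = 0.00013). None of these list differences kept its call throughout (0): those of R75 lost it without control 1 (-2.63 and 1.81), those of Nipponbare, Kasalath and A58 without either control, and those of Kirara without control 1 (-0.10 for meiosis and 1.00 for the transcription factors).

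The cytochrome P450 Os08g0131100 was not above background in Kasalath controls, at least 5601-fold lower than in the others, and the anther-specific gene Os11g0582500 not in Fukoku controls, at least 282-fold lower. Other low levels were those of the eggshell family gene Os05g0498200 in Nipponbare (at least 1089-fold), and a bisphosphate nucleotidase (Os12g0183300) in Sasanishiki and Koshihikari (at least 328-fold and 401-fold). So were those of callose synthase 1 (Os06g0112800) in Lambayeque1 (at least 1523-fold), a ribonuclease H fold gene (Os01g0944200) in R45 (at least 581-fold) and a phosphodiesterase (Os02g0588500) in R85 (at least 197-fold). A histone H2B gene (Os01g0152700) lay lower in PL9 by -9.21 ± 0.31 log2, and a thaumatin (Os04g0165000), above background on 11 of the 24 other controls, higher in H287 by 7.43 ± 2.15. A lipid transfer domain gene (Os04g0415900) was above background on both A58 controls and on only 2 of the 24 others, so no size is given for its difference. The adjusted p-values of the genes in this comparison ran from 2.2e-29 to 0.043. In all, 20612 genes (85.9%) differed between controls by the F-test. In a separate comparison of each line with the others, A58, whose arrays were dim, had 15274. Of the 13 differences, in 12 genes, 3 lost the call without 1 control of their line (Os11g0582500, Os08g0473900 and Os04g0165000). A probe can read a sequence difference of a line as a level, which these arrays cannot separate from expression.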

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

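The patterns in PL9 and Kirara were chosen for weighing after the counts had been seen, and the tests of stress in the Kirara controls, of the replicates of PL9 itself and of the Kirara difference without control 1 were chosen after related values had been seen. The bound of the last was written after its value was known. No group has 4 to 10 samples, so no single array was tested for standing apart from its group.

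The lines differed in their response to cold. The F-test between lines called 1151 genes, and the mean of the photosynthesis list, also a marker of green tissue, differed between lines at an adjusted p of 0.00017. Against the other lines, the number of genes with a different cold effect was 311 in Nipponbare, 2 in Sasanishiki, 13 in Koshihikari, 2 in Fukoku, 325 in A58, 1897 in PL9, 116 in Lambayeque1, 79 in Kasalath, 476 in Kirara, 63 in R45, 73 in R75, 2 in R85 and 6 in H287. These counts moved far when 1 array was left out, to 20 or 5115 in Kirara, to 542 in PL9 and to 1017 in H287. Probes outside the gene comparison also gave a signal: of 218 miRNA probes, 20 were higher and 13 lower in cold, of 8604 repeat probes 601 and 479, and of 6584 probes antisense to repeats 388 and 350.

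The average cold effect called 12519 genes. Of 100 splits of the arrays within lines, 1 gave as many, the real one, and the highest of the others gave 520. This argues against chance in how these arrays were divided. If the replicates of a group are technical, the splits cannot address chance differences between plants. The data argue against the place of an array on its slide as the whole cause, since Nipponbare, with cold in place 1 and control in place 2, had a median correlation across genes of 0.323 with the other lines, just above the bound of 0.3 set beforehand. For the other 12 lines place and treatment coincide, so a share of the effect could come from it. A biological effect of cold stays open and was not tested apart from this. Nor was it tested apart from a difference of anther stage, or of time of collection, between cold and control. The mean of the meiosis list was lower in cold by -0.46 log2 (limma adjusted p = 0.0057), while those of the tapetum and pollen maturation lists were not called.

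PL9 had the most genes with a cold effect (5588), and was first in 11 of 15 settings. The spread of its changes was 1.32 times that of the next line with a pooled error taken off, a value past the bound set beforehand that decides nothing because the error was almost equal in all lines (mean square 0.438 to 0.441), and 1.27 times with each line's own (1.33 under quantile normalization), past the same bound of 1.2. Noise of its replicates is still left open, by a condition added after these values were seen, that the ratio hold without any 1 PL9 array: without control 2 the pooled ratio was 1.12, as a single control gives no variance of its own. PL9 was also at rank 3 with array weights, below Nipponbare (7200) and Lambayeque1 (5703), and at rank 6 with the arrays of a line alone, while scaling may account for the rank of PL9 against the dim arrays of A58 (4670 and 4794 genes under quantile normalization, a ratio of 0.974), although PL9 was first with median centring (5083 against 1893), over probes above background (5691 against 2477) and with normexp (4731 against 3759). The stage of the anthers and a difference of the line itself stay open, since the tapetum list in PL9 differed from the other lines by -1.09 log2 with an adjusted p of 0.52. The pollen maturation list differed by -0.66 (limma adjusted p = 0.065), nearest to a call, and the meiosis list by -0.50 (adjusted p = 0.62).

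Kirara showed no rise of the cold-responsive transcription factors (-0.70 ± 0.53 log2). The weak signal of its control 1 is left open as a cause. Without that array the effect in Kirara was -0.43, below the bound of 0 set beforehand but within its SE of 0. Kirara still lay below the other lines by -1.67 ± 0.68 log2, which was not called over all lists. That difference decides nothing, because it rests on 1 control array and its bound in SE was written after the value was known. The list lay above the other controls in the Kirara controls by 1.27 log2 (limma adjusted p = 0.02), but by 1.00 and without a call when control 1 was left out. These control values also enter the missing rise itself, so they restate part of it. They cannot tell stress in the control anthers from any other cause of a high control value. The control values rest on 2 arrays, and a difference of the line itself, or of how its plants were handled, was not tested.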

How the results depend on the processing

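Chosen after seeing the data were the scaling over probes above background on all arrays, leaving out A58, leaving out the 2 arrays of low detection, list members as written and each scan day alone; the other alternatives were set beforehand. Under the scalings run, 5831 to 6657 genes were higher on average and 5641 to 6198 lower. More genes were lower than higher with median centring (5831 higher, 6147 lower), against more higher with the others. Leaving out 1 array gave 6436 to 6893 higher and 5631 to 6308 lower. Of 13800 values under alternatives of results on named genes, lists and counts of single comparisons, 13291 kept their direction and side of the threshold, 239 lost the call, 85 gained one, 180 counts or values without a test moved and 5 reversed, and 137 of 236 results kept throughout. Counts within single lines rest on 2 arrays a side and moved far more. The cause was not tested except where fewer genes, lines or arrays entered by construction. Low signal over background limits A58 most, and the 2 arrays of low detection, Kirara control 1 and H287 cold 2.

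With normexp, 472 genes were higher and 473 lower by 2-fold or more. Called genes were then 481 in Sasanishiki, 3759 in A58, 669 in Lambayeque1, 996 in Kasalath and 960 in R45, and the spread was 0.63 in A58, 0.85 in PL9, 0.40 in Lambayeque1, 0.45 in Kasalath and 0.44 in R45. Quantile normalization gave 395 in Sasanishiki, 693 in Koshihikari, 1191 in Fukoku, 4794 in A58, 604 in Lambayeque1, 857 in Kasalath and 328 in R85, with 4874 line-specific genes and spreads of 1.17 in A58 and 0.67 in Kasalath. The deposited values gave, in the same order, 369, 642, 1124, 4764, 580, 802 and 320, with 4806 line-specific genes and spreads of 1.17 and 0.67. Median centring gave 323 in R85.

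Keeping probes above background on all 52 arrays, which tests fewer genes, left 2639 higher and 1938 lower, 240 and 127 of them by 2-fold. Called genes were 696 in Nipponbare, 327 in Sasanishiki, 298 in Koshihikari, 705 in Fukoku, 663 in A58, 2161 in PL9, 526 in Lambayeque1, 608 in Kasalath, 965 in Kirara, 710 in R45, 588 in R75, 158 in R85 and 942 in H287. The F-test then called 346, the line-specific comparison 1024 and the controls 6548. The spread was 0.88 in PL9 and 0.55 in Kasalath, and the median and highest correlations were 0.49 and 0.75.

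Array weights gave 7200 genes in Nipponbare, 3088 in Sasanishiki, 2968 in Koshihikari, 282 in A58, 5703 in Lambayeque1, 3908 in Kasalath, 60 in Kirara, 661 in R45, 2121 in R75, 2524 in R85 and 647 in H287, with 6943 by the F-test, 5878 line-specific, and spreads of 0 in A58 and 0.31 in Kirara. With a replicate block, Sasanishiki had 477, Koshihikari 809, R85 289 and the F-test 355. With the slide as a fixed block, Nipponbare had 712. Without the 2 arrays of low detection, Sasanishiki had 1233, Koshihikari 2168, Kirara 1468, R85 849 and H287 1064. The arrays of a line alone gave 7105 in Nipponbare, 638 in A58, 541 in PL9, 3168 in Lambayeque1, 45 in H287 and 0 in Sasanishiki, Koshihikari, Fukoku, Kirara, R45 and R85, from fewer arrays. The lines of scan day 1 alone, which are fewer, gave 2407 higher and 2272 lower.

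Of the lists, camera with an estimated correlation called 0 higher and 0 lower, and fry 11 and 4. Of 80 alternatives, 16 called the WRKY list, 10 starch synthesis and 5 ribosomal proteins. Lists lower were 4 without Lambayeque1, without R45 or without the 2 arrays of low detection, and 2 to 4 with 1 array left out (4 without Koshihikari cold 2 or Kirara control 1). Directions reversed for Os03g0243300 with the mean of its probes (0.26) and another probe (0.98), and with another probe for Os02g0790500 (-0.075), Os03g0856700 (-0.69) and Os10g0471100 (-0.12).

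With 1 array left out, its group's other array is assumed to vary like the other groups. Called genes ran from 365 to 1346 in Nipponbare (396 without control 1, 388 without control 2, 365 without cold 2), 144 to 260 in Sasanishiki (260, 144, 173 and 144 without control 1, control 2, cold 1 and cold 2), and 23 to 1559 in Koshihikari (648, 130 and 23 without control 1, control 2 and cold 1). They ran from 292 to 1957 in Fukoku (698, 399 and 292 without control 1, control 2 and cold 2), 837 to 1657 in A58 (837 without control 2) and 2693 to 4057 in PL9 (2693 without control 2). Lambayeque1 ran from 435 to 649 (435, 554, 649 and 470 without control 1, control 2, cold 1 and cold 2), Kasalath from 590 to 874 (590, 649, 874 and 708 in that order), and Kirara from 670 to 5353 (1354, 5353, 689 and 670). R45 ran from 668 to 1279 (668 and 856 without control 1 and cold 1), R75 from 302 to 711 (708, 711, 302 and 591 in the order above), R85 from 102 to 167 (167, 139, 141 and 102), and H287 from 692 to 2515 (747 and 692 without control 1 and cold 2).

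The F-test ran from 691 to 4220 (691, 704 and 759 without Nipponbare control 1, control 2 and cold 2, 732 without PL9 control 2, 4220 without Kirara control 2 and 1755 without H287 cold 1). Line-specific genes ran from 1732 (without PL9 control 2) to 7866 (without Kirara control 2). By line they ran from 23 to 703 in Nipponbare, 2 to 7 in Sasanishiki, 1 to 32 in Koshihikari, 2 to 74 in Fukoku, 260 to 817 in A58, 542 to 1597 in PL9, 44 to 122 in Lambayeque1, 29 to 82 in Kasalath, 20 to 5115 in Kirara, 87 to 155 in R45, 17 to 54 in R75, 12 to 22 in R85 and 2 to 1017 in H287.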

Other observations

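The counts of repeat families below were chosen after the data were seen and are given as values alone.

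Probes for transposable elements on the same arrays were counted by family; families were not tested against each other, and most probes of each were not called. Of 5458 probes for putative MITEs, which are short DNA transposons, 471 were higher in cold and 263 lower. Castaway-like elements had 64 of 343 probes higher and 0 lower, and MITE-adh elements of type D had 127 of 1126 higher and 18 lower. MITE-adh elements of type M had 35 of 211 lower and 1 higher. Gaijin-like elements had 63 of 1287 higher and 96 lower, Ditto-like elements 121 of 1304 higher and 76 lower, and unclassified transposons 51 of 1269 higher and 126 lower. Of 125 probes in the separate retrotransposon class of the array, 16 were higher and 9 lower. Among the repeat probes, putative retrotransposons had 9 of 117 higher and 10 lower, and unclassified retrotransposons 0 of 34 higher and 6 lower. A probe for a repeat can read several copies, or a gene that holds one.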
